A study of Mus musculus with 29 samples.

How the data were processed

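Gene expression in the hypothalamus of C57BL/6 wild-type mice, all labelled male, was measured by paired-end RNA sequencing at 9 ages from postnatal day 5 (P5) to 24 months. Per the labels, the mice were singly housed under 12 h of light and 12 h of dark, and tissue was taken about 6 h after lights on and kept in RNAlater. Each age had 3 or 4 deposited libraries: 4 at 4 and at 5 weeks, and 3 at each other age, which makes 29. Most sample titles hold the letters th, tha or thal, and the tissue label, hypothalamus, was used. Replicates were read as separate mice from their labels. Where the labels say no more than that, p-values measure the spread between these libraries.

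Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to the mouse genome (mm10, GRCm38) and counted per gene with HTSeq 0.9.1. The deposited values are counts per gene symbol, 1 file per library, for 24499 symbols and 5 HTSeq summary lines. The annotation, the strand setting and any read trimming are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical gene copies are uncertain. This holds for the clustered protocadherins, the hemoglobin genes, Rn7s1 and Rn7s2, the H2 genes, Ly6a and Ly6c1, and Dcpp1 to Dcpp3. Of the symbols, 23688 have a position in GENCODE release M21 (GRCm38), and positions in the text are from that release. The HTSeq summary lines held 26.1 to 32.5% of the total per library and were removed.

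Values in CPM (counts scaled to the library size) were computed here from the deposited counts with library sizes scaled by the trimmed mean of M-values (TMM). Log2 values used a prior count of 1. A library held 24661631 to 39783779 gene counts, so that 3 counts made about 0.1 CPM. Intervals given for ratios of counts cover counting error only. Intervals of list medians and of slopes over genes came from resampling genes, so they do not hold the spread between mice. Errors after ± are 1 SE for log2 fold changes and slopes, and 1 SD between libraries for CPM.

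The third 24-month library (replicate 5) held 2377580 counts in 1385 genes, and the 1341 of these with a position all lie on chromosomes 1 and 10. It was left out, which departs from the plan of 3 libraries at 24 months, and 28 libraries were used. The 24-month age therefore rests on 2 libraries. A fit with all 29 was run as an alternative.

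Genes were filtered with filterByExpr by age, which left 16916, and fitted with the quasi-likelihood method of edgeR 4.0.16 (robust; R 4.3.3) with 1 mean per age. Tests were two-sided. Comparisons were 3 weeks against P5, 5 weeks against 3 weeks, 2 months against 5 weeks, 12 against 2 months, 24 against 12 months, 24 against 2 months, and an F-test over the 9 ages. A separate fit gave the slope of log2 expression per month of age over the 14 libraries from 2 to 24 months (16633 genes), called the adult age trend. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a gene was called below an adjusted p of 0.05. All adjusted p-values of genes are from edgeR unless DESeq2 is named.

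For gene groups, 52 lists of cell types, pathways and regions, with 985 genes (970 found in the files, 37 in more than 1 list), were written before the data were examined. Lists with at least 5 tested members (51, or 50 for the adult age trend) were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, adjusted over lists. An estimated correlation was the alternative, and its p stands beside each list it removes. Beside the members called among all genes, counts are given of members called with p-values adjusted over the list alone. A list of 21 tested midbrain and hindbrain markers, further marker lists for these regions and the salivary gland, and tests of list levels per library were added after the values were seen. Those library tests used exact splits or 100000 permutations, two-sided, on the mean log2 CPM of a list.

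The choice of groups, comparisons, tests, thresholds, lists and named genes was made before the data were examined. Named genes were (a) the 6 highest and 6 lowest fold changes among called genes with a mean of at least 5 CPM in the higher age and no overlap between the libraries of the ages compared (for the trend, the 6 rising and 6 falling genes of smallest p with at least 5 CPM at any age); (b) up to 4 called members of each called list, smallest p first; and (c) a panel of genes given whatever their result. Symbols of the Gm-number, Rik and -ps kinds were passed over in (a). Some genes chosen by (b) and (c) are not reported here. A gene at 0 in every library of an age was compared with a floor of 3 counts over the group.

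The tests were checked on simulated counts of the same sizes, with changes planted in genes with a mean of at least 1 CPM. Genes were drawn independently, with no shared effect of dissection or batch. The false calls below are therefore not the error rate in these data. Planted changes of 1.5-fold were recovered for 68.7% of genes (3 weeks against P5), 74.6% (5 against 3 weeks), 61.2% (2 months against 5 weeks), 68.7% (12 against 2 months), 59.7% (24 against 12 months), 62.7% (24 against 2 months) and 65.7% (trend). For 2-fold changes these were 85.1, 82.1, 79.1, 85.1, 80.6, 82.1 and 88.1%, and for 4-fold changes 98.5, 93.9, 100, 98.5, 98.5, 95.5 and 95.5%. False calls numbered 2, 10, 10, 10, 7, 9 and 12 in the same order.

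Alternatives were DESeq2 1.42.0, its size factors within edgeR, other filters, 1 surrogate variable (sva 3.50.0), the replicate number as a block, only the ages compared, each library left out in turn, log2 age and the trend without 24 months. Added after the data were seen were all 29 libraries, 6 months in place of 2 months, no 2-month libraries, P5 replicate 3 alone, a library batch term from 3 to 5 weeks, and covariates for midbrain and hindbrain or choroid plexus markers. The 31 pairs of libraries of the same age differed beyond counting error (chi-squared per degree of freedom 5.42 to 58.49), and none were identical.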

Results

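RNA of the hypothalamus was counted in 28 libraries of wild-type mice: 3 at postnatal day 5 (P5), 3 at 3 weeks, 4 at 4 weeks, 4 at 5 weeks, 3 each at 2, 6, 12 and 18 months, and 2 at 24 months. Depth was 24661631 to 39783779 gene counts per library. It was 29954951 to 35101585 at P5, 24661631 to 27936518 at 12 months and 32341783 to 32555195 at 24 months. The first principal component of the 2000 most variable genes held 39.7% of the variance and set P5 (-90.3 to -81.6) apart from every later library (-10.3 to 21.9). The second, with 15.3%, ran from the 3-week libraries (-28.6 to -25.7) to those of 12 and 18 months (18.2 to 35.1). Of 16916 tested genes, 12991 (76.8%) differed between the 9 ages at an adjusted p below the threshold.

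**Figure D1:**
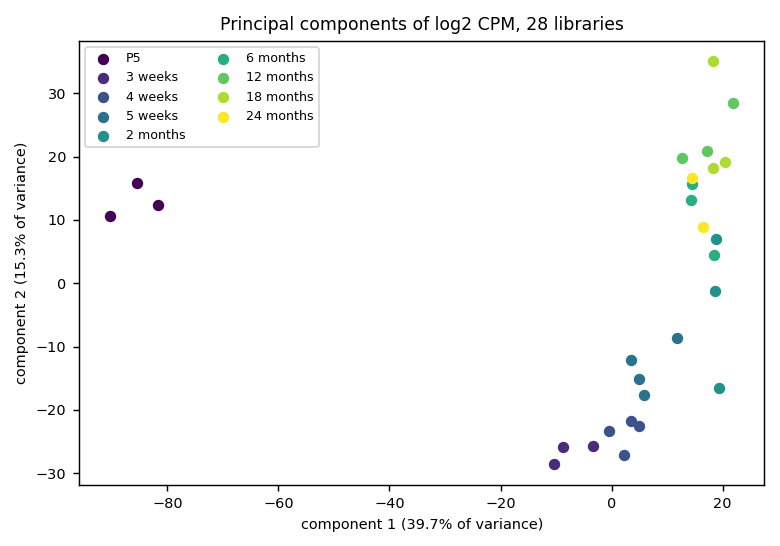
Principal components 1 and 2 of log2 CPM in 28 libraries, colored by age. P5 lies apart on component 1, and later ages spread along component 2.

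The markers of each library's sex and tissue differed between some libraries. At P5, replicates 1 and 2, which are labelled male, held Xist, the RNA of the inactive X chromosome, at 746 and 791 CPM and no counts of the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. Replicate 3 held 0.223 CPM of Xist and 55.1 CPM of Ddx3y, and the later libraries at most 1.19 CPM of Xist and 54.5 to 104 CPM of Ddx3y. Ttr, which the choroid plexus makes in large amounts, ranged from 1.17 to 4550 CPM over the libraries. The 2-month libraries held little Avp (16.5, 11.1 and 56.9 CPM) and Oxt (3.41, 7.54 and 22.3 CPM), the vasopressin and oxytocin genes.

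To ask how the hypothalamus changed from the first postnatal week to weaning, 3 weeks was compared with P5 (3 libraries each). As P5 replicates 1 and 2 held Xist and no Y-linked counts, unlike the 3-week libraries, sex is partly mixed with age here. Genes of myelin rose to high levels: Mobp went from 1.75 ± 0.814 to 1190 ± 147 CPM (log2 fold change 9.40 ± 0.28, adjusted p = 1.27e-17) and Mal from 2.62 ± 0.324 to 752 ± 97.1 CPM. Mbp, which encodes myelin basic protein, went from 163 ± 36.1 to 9740 ± 1010 CPM (59.7-fold). Genes of growing and migrating neurons fell. Dcx, a microtubule protein of migrating neurons, went from 400 ± 42.2 to 21.5 ± 1.96 CPM (-4.22 ± 0.25, adjusted p = 2.11e-12), and Dpysl3, which acts in growth cones, from 2110 ± 92.3 to 123 ± 5.44 CPM (-4.10 ± 0.10). In all, 9986 genes changed, 5034 up and 4952 down, of which 1647 and 1534 changed by at least 2-fold.

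The list of myelin and mature oligodendrocyte genes had all 22 of its members risen (22 over the list alone, median log2 change 5.20, adjusted p = 1.32e-76, 0.00104 with an estimated correlation). Called members included Mag (5.81 ± 0.17), Cldn11 (6.22 ± 0.19) and Mog (5.16 ± 0.16). Opalin, an oligodendrocyte membrane protein, had 2 counts at P5 against 4682 at 3 weeks, a ratio of 2360 (interval 653 to 19500), and the protease Klk6 1 against 719 (ratio 725, 130 to 28700). Of 25 proliferation genes, 25 fell (25 over the list alone, median -2.22, adjusted p = 3.27e-12). Among these were the replication genes Mcm6 (-1.86), Rrm2 (-2.89) and Mcm2 (-1.50) and the mitotic gene Cenpf (-2.74). Mki67, a marker of dividing cells, fell from 30.6 to 3.43 CPM. Of 22 genes of progenitors and immature neurons, 20 fell and none rose (21 over the list alone, median -1.77, adjusted p = 2.56e-24). Examples were Crmp1 (-2.51), Dpysl5 (-3.02), Mex3a (-3.53) and Draxin (-5.68), an axon guidance protein.

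Glia and vessels moved as well. Of 18 astrocyte genes, 16 rose and 1, Aldh1l1, fell (16 and 1 over the list alone, median 1.04, adjusted p = 6.98e-09, 0.131 with an estimated correlation). The glutamate transporter Slc1a2 rose from 388 to 1390 CPM (1.84 ± 0.10), Ntsr2 by 3.21 and the gap junction gene Gjb6 by 3.26, and the lipid enzyme Etnppl from 0.212 to 62.2 CPM. Of 18 homeostatic microglia genes, 17 rose (18 over the list alone, median 1.02, adjusted p = 7.82e-07, 0.462 with an estimated correlation), led by Selplg (2.88 ± 0.15) and Tmem119 (2.56 ± 0.16). In the list of disease-associated microglia, 13 of 22 rose and Lgals3 fell (13 and 1 over the list alone; adjusted p = 0.0452, 0.701 with an estimated correlation). Called members included the lysosomal Ctsd (0.99) and Ctsb (0.69). Interferon-response genes rose in 22 of 30 cases and fell in 1 (the same counts over the list alone, median 1.45, adjusted p = 0.000254, 0.701 with an estimated correlation): Irf7 went from 0.653 to 3.52 CPM and Ifit3 from 0.763 to 6.61. Endothelial genes rose in 11 of 17 cases, and 1 fell (12 and 1 over the list alone; adjusted p = 0.000383, 0.468 with an estimated correlation). Among these were the transporters Slco1a4 (2.40) and Slc2a1 (1.39).

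Neuronal function genes rose in part. Of 20 ion channel genes of mature firing, 13 rose and 2 fell (13 and 2 over the list alone, median 1.29, adjusted p = 0.00201, 0.618 with an estimated correlation): the potassium channel Kcnc2 rose by 2.51 ± 0.20. Of 30 synaptic genes, 17 rose and 5 fell (17 and 5 over the list alone, median 0.40, adjusted p = 0.0327, 0.701 with an estimated correlation). An example was Snap25, of the vesicle fusion machinery, at 1.54 ± 0.13. The NMDA receptor gene Grin1 rose by 0.81 and Grin2b fell by 0.82 (adjusted p = 0.0319), while the chloride extruder Slc12a5 rose by 0.35 (adjusted p = 0.00263). Slc6a4, the serotonin transporter, fell from 17 ± 15 to 0.119 ± 0.136 CPM (-7.04 ± 1.60). Of 19 clock genes, 15 rose and Nfil3 fell (15 and 2 over the list alone, median 1.16, adjusted p = 7.52e-08, 0.0241 with an estimated correlation). Called members included Tef (1.76 ± 0.08), Bhlhe41 (2.02 ± 0.09) and Nr1d1 (1.73 ± 0.11), all from tissue taken near 1 time of day. Of 15 thyroid hormone-responsive genes, 9 rose and 3 fell (10 and 3 over the list alone; adjusted p = 1.8e-07). Hr (2.76), Itih3 (3.72) and the potassium channel Kcnj10 (2.39) were among the risen genes.

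DNA methylation genes fell in 11 of 14 cases and rose in 2 (the same over the list alone; adjusted p = 0.0202, 0.618 with an estimated correlation): the methyltransferase Dnmt3a went from 454 ± 15.2 to 166 ± 15.8 CPM, and Mbd2 rose by 0.96. Cytosolic ribosomal protein genes fell in 44 of 76 cases and rose in 3 (the same over the list alone, median -0.31, adjusted p = 0.00149, 0.779 with an estimated correlation). Nuclear genes of the respiratory chain rose in 35 of 56 cases, with 1 fallen (the same over the list alone; adjusted p = 0.0016, 0.779 with an estimated correlation). Mitochondrially encoded genes rose in 12 of 13 (12 over the list alone; adjusted p = 0.0232, 0.701 with an estimated correlation). Blood cell genes rose in 7 of 8 cases (8 over the list alone; adjusted p = 0.0452, 0.701 with an estimated correlation). One was Alas2, of heme synthesis in red cells, at 24.6 ± 9.02 against 3.20 ± 0.554 CPM. The growth factor gene Igf2 (-0.19 ± 0.51, adjusted p = 0.771) and Gnrh1, the gonadotropin-releasing hormone gene (0.23 ± 0.64, adjusted p = 0.777), did not pass the test. Gfap rose by 1.44 (adjusted p = 0.00176), and Lefty2, an inhibitor of nodal signals (-6.02), Hsd11b2, which inactivates corticosteroids (-5.35), the adhesion gene Cxadr (-4.49) and Dkkl1 (-4.38) fell. With the Xist-free P5 library (replicate 3) alone on the P5 side, which assumes that it varies like the other ages, 7742 genes changed. Bpifa2, a salivary gland protein gene, had 3864 counts at 3 weeks against 1 at P5 (ratio 3890, 698 to 154000).

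**Figure D2:**
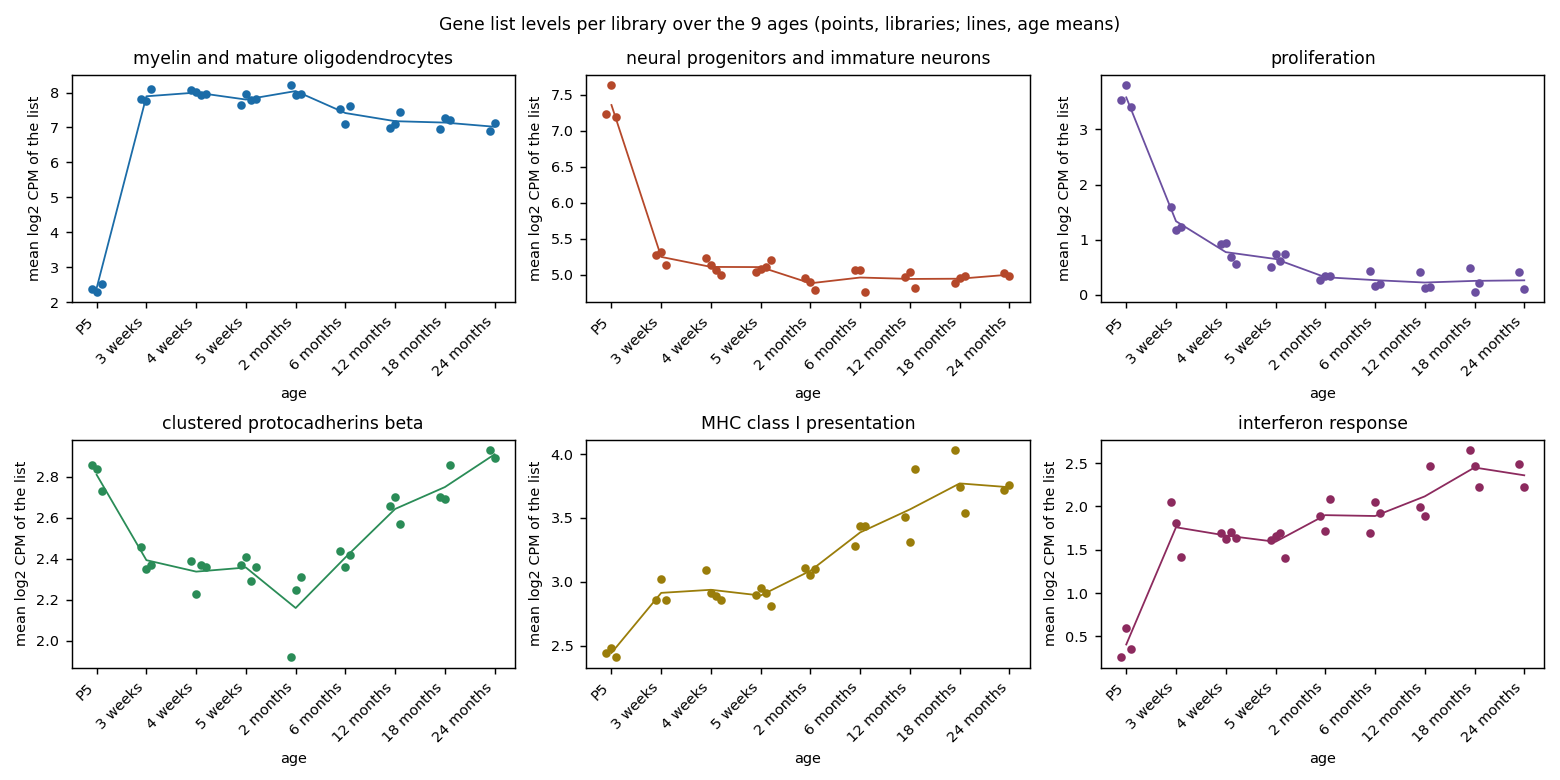
Mean log2 CPM of 6 gene lists in each of 28 libraries over the 9 ages. Myelin genes rise and progenitor and proliferation genes fall between P5 and 3 weeks; protocadherin, MHC class I and interferon genes lie higher at the older adult ages.

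The weeks around puberty were examined by comparing 5 weeks (4 libraries) with 3 weeks (3). Far fewer genes changed, 363 (118 up and 245 down, of which 22 and 42 by at least 2-fold; 183 to 256 when 1 library was left out), and those of the red blood cell and of young oligodendrocytes stood among them. Alas2 fell from 24.6 ± 9.02 to 4.76 ± 1.97 CPM (-2.37 ± 0.32, adjusted p = 0.000129). Gpr17, a receptor of oligodendrocytes on the way to myelination, fell from 230 ± 11.1 to 107 ± 10.2 CPM (-1.11 ± 0.12, adjusted p = 4.51e-06). The protease inhibitor gene Serpinb1a rose from 2.9 ± 0.462 to 16.7 ± 2.77 CPM (2.53 ± 0.28), Tnfaip6, of the hyaluronan matrix, by 1.77 ± 0.19, and the nuclear RNA Neat1 by 1.43 ± 0.26.

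Of 8 blood cell genes, 7 fell and none rose (8 over the list alone, median -2.12, adjusted p = 2.95e-23). Called members included Slc4a1 (-2.70) and the hemoglobin gene Hbb-bt (-2.09, its copies uncertain). Of 14 oligodendrocyte precursor genes, 8 fell (8 over the list alone, median -0.44, adjusted p = 5.72e-19). Among these were Enpp6 (-0.87), Itpr2 (-0.55) and Pdgfra (-0.39). Proliferation genes fell in 6 of 25 cases (13 over the list alone, median -0.53, adjusted p = 1.22e-12). Examples were Top2a (-1.51) and Mki67 (-1.31). Progenitor genes fell in 4 of 22 (4 over the list alone; adjusted p = 4.05e-06). Called members included Marcksl1 (-0.70) and Sox4 (-0.57). Clock genes rose in 5 of 19 cases (7 over the list alone, median 0.27, adjusted p = 5.25e-09). Among these were Nr1d1 (0.60 ± 0.10) and Ciart (0.69 ± 0.15). These 5 lists also passed with an estimated correlation (adjusted p = 0.00123, 0.00123, 0.0257, 0.0439 and 0.018 in the order given, clock genes last).

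The following lists were called at the preset correlation alone. Extracellular matrix genes fell (4 of 27, 7 over the list alone; adjusted p = 3.06e-08, 0.184 with an estimated correlation). Examples were the basement membrane genes Lama4 (-0.77), Nid1 (-0.84) and Col4a1 (-0.78). Chaperones fell too (5 of 20, 7 over the list alone; adjusted p = 5.27e-08, 0.257 with an estimated correlation). Called members included Calr (-0.42) and Hspa5 (-0.39) of the endoplasmic reticulum. Cholesterol synthesis (1 of 24 fell; 6 over the list alone; adjusted p = 0.000736, 0.78 with an estimated correlation) and homeostatic microglia (1 of 18 fell, Fcrls; 1 over the list alone; adjusted p = 0.000198, 0.639 with an estimated correlation) had a single called member each. Of 16 glucocorticoid-responsive genes, 2 rose, Mt2 (0.90) and Zbtb16 (0.83), and over the list alone 4 rose and 1 fell (adjusted p = 0.000755, 0.423 with an estimated correlation). With the library batch as a term that list went down (adjusted p = 0.000863). Thalamus genes had a median of 0.24 and none of 18 members called (adjusted p = 0.00921, 0.897 with an estimated correlation), and striatum genes a median of -0.72 and none of 13 called (adjusted p = 0.00131, 0.78 with an estimated correlation). The lists of B cells (3 of 6 lower over the list alone), border macrophages, senescence and the nuclear respiratory chain (none over the list alone) were called downward with no member called among all genes (adjusted p = 0.139, 0.78, 0.197 and 0.931 with an estimated correlation).

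None of the 22 genes of puberty and the reproductive axis were called among all genes, and 1 was over the list alone (list adjusted p = 0.813). Gnrh1 had a log2 change of 0.14 ± 0.59 (adjusted p = 0.962), Kiss1, the kisspeptin gene, 0.44 ± 0.51 (0.833), Tac2 0.04 ± 0.23, Pdyn -0.17 ± 0.19, Esr1 -0.45 ± 0.20 (0.38), Mkrn3 -0.57 ± 0.21 (0.22) and Lin28b 0.06 ± 0.27. At unadjusted p below 0.05, edgeR gave 1972 genes in the whole comparison.

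The libraries of 3 to 5 weeks fell into 2 sets on a salivary gland transcript and on 7SL RNA. Bpifa2 was at 34 to 47 CPM in the 3-week libraries and in 4-week replicates 1 and 2, and at 0 in 4-week replicates 3 and 4 and at 5 weeks (at least 1420-fold higher at 3 than at 5 weeks). The 7SL RNA copy Rn7s2 was at 21.7 to 29.6 CPM in 4-week replicates 3 and 4 and at 5 weeks, against 1.44 to 2.11 CPM in the other 5 libraries. With this set as a term in the fit, 20 genes were called, 14 of them among the 363 in the same direction. The chitinase gene Chia1 went from -2.09 to 0.13. The clock list lost its call with the term (camera at the preset correlation, adjusted p = 0.143). The blood cell, precursor and proliferation lists kept theirs at the preset correlation (3.68e-06, 3.68e-06 and 0.0243). With the term and an estimated correlation none of them passed (camera, adjusted p = 0.113, 0.0821 and 0.651).

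**Figure D3:**
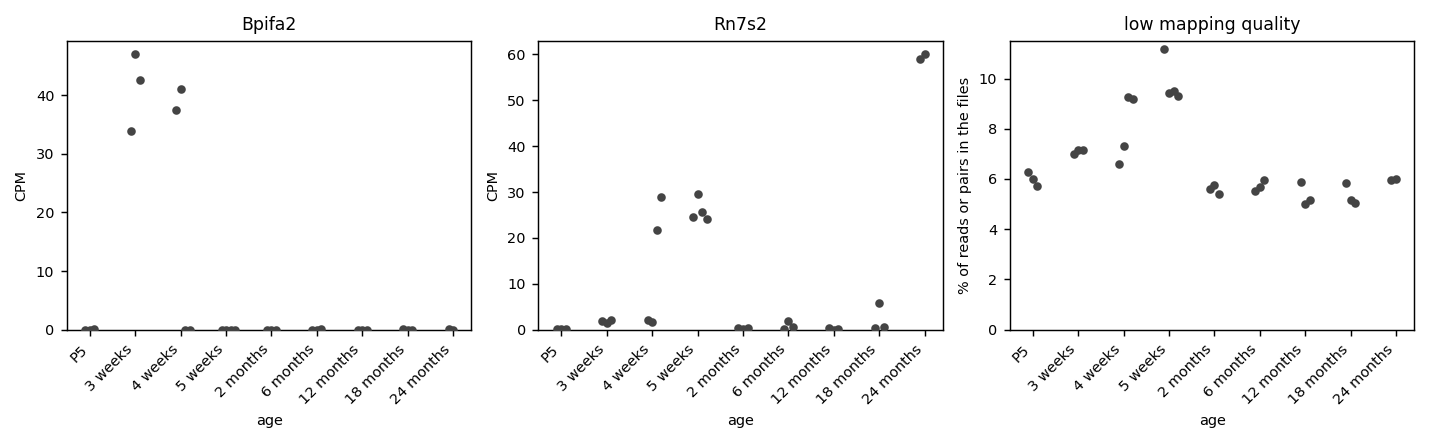
Bpifa2 and Rn7s2 (CPM) and the share of reads of low mapping quality in 28 libraries by age. In the weeks around weaning, both transcripts part the libraries within 4 weeks.

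To follow the step into adulthood, 2 months (3 libraries) was compared with 5 weeks (4), and genes typical of the hypothalamus fell while single markers of the midbrain and hindbrain rose. Oxt fell from 162 ± 50.3 to 11.1 ± 9.91 CPM (-3.89 ± 0.50, adjusted p = 6.59e-05) and Avp from 299 ± 73.3 to 28.2 ± 25.1 CPM (-3.42 ± 0.57, adjusted p = 0.000583). The ventromedial hypothalamic regulators Fezf1 (-3.28 ± 0.53) and Nr5a1 (-2.97 ± 0.72) fell as well. Tfap2b rose from 0.377 to 11.2 ± 6.39 CPM (4.88 ± 0.64, adjusted p = 5.63e-05), Gata3, a regulator of midbrain and hindbrain neurons, from 0.520 to 8.47 CPM, Tal1 by 2.40, and the peptide genes Ucn by 4.21 and Rln3 by 2.90. In all, 2802 genes changed (1206 up and 1596 down, of which 142 and 161 by at least 2-fold). The 7SL RNA copy Rn7s2 fell too, from 24.2 to 29.6 CPM in the 5-week libraries to 0.177 to 0.435 CPM at 2 months. The share of low mapping quality was 9.31 to 11.2% at 5 weeks and 5.41 to 5.77% at 2 months. The 2 ages thus also differ in a marker that parts the libraries of 3 to 5 weeks, and a batch cannot be told apart from age here.

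Of 25 hypothalamic transcription factors, 17 fell and Sox14 rose (19 and 1 over the list alone, median -1.35, adjusted p = 7.87e-14, 0.126 with an estimated correlation). Among these were Otp (-2.90 ± 0.37), Vax1 (-2.73 ± 0.41) and Six6 (-2.61 ± 0.33). Of 30 hypothalamic neuropeptides, 14 fell and 2 rose (17 and 2 over the list alone, median -1.07, adjusted p = 2.55e-10, 0.168 with an estimated correlation): Trh (-2.10), Gal (-1.69) and Pomc (-1.62, adjusted p = 0.00844) fell, and Cartpt and Grp rose. Of 22 puberty genes, 7 fell (9 over the list alone, median -0.49, adjusted p = 2.62e-06, 0.187 with an estimated correlation). Examples were Gpr101 (-1.24) and Npffr1 (-1.48). Imprinted growth genes fell in 6 of 17 cases (9 over the list alone, median -0.43, adjusted p = 0.00085, 0.579 with an estimated correlation). Called members included Magel2 (-1.16) and Peg10 (-0.99). Of 21 midbrain and hindbrain markers picked from these data, 9 rose, while of 24 others, written before they were measured, 1 rose and none fell (median 0.13, interval -0.20 to 0.52).

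Genes of maturing glia moved in the same comparison. Myelin genes rose in 7 of 22 cases (7 over the list alone, median 0.19, adjusted p = 0.0033, 0.603 with an estimated correlation), with Apod (1.12), Trf (0.79) and Hapln2 (0.66), while Mbp did not pass the test (0.24 ± 0.18, adjusted p = 0.379). The list lost its call without 2-month replicate 11 (adjusted p = 0.103), as 11 of the 22 called lists did without 1 library, and with 6 months in place of 2 months it went down (adjusted p = 1.76e-06). Oligodendrocyte precursor genes fell in 3 of 14 (3 over the list alone; adjusted p = 0.00298, 0.579 with an estimated correlation). Gpr17 fell again, from 107 ± 10.2 to 51.9 ± 11.4 CPM (-1.04 ± 0.13, adjusted p = 3.48e-05). Progenitor genes fell in 7 of 22 (10 over the list alone; adjusted p = 0.00037, 0.222 with an estimated correlation). Examples were Sox4 (-0.89) and Tubb3 (-0.35), while Dcx did not pass the test (-0.07 ± 0.22, adjusted p = 0.869). Astrocyte genes rose in 8 of 18 and Slc1a3 fell (9 and 1 over the list alone; adjusted p = 0.00122, 0.579 with an estimated correlation). Called members included the glutamine synthetase gene Glul (0.69) and S100b (0.89). Among cytokine genes, the alarmin Il33 rose from 37.2 ± 3.76 to 89 ± 14 CPM (1.26 ± 0.16, adjusted p = 4.01e-05; list 3 of 15 risen, 5 over the list alone, adjusted p = 0.0493, 0.579 with an estimated correlation).

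Ribosomal protein genes rose in 30 of 76 cases and none fell (44 over the list alone, median 0.28, adjusted p = 7.87e-14, 0.603 with an estimated correlation). Nuclear respiratory chain genes rose in 24 of 56 (32 over the list alone; adjusted p = 3.19e-11, 0.603 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 13 (7 up and 1 down over the list alone; adjusted p = 0.000173, 0.579 with an estimated correlation). Ion channel genes rose in 8 of 20 cases and fell in 3 (9 and 3 over the list alone; adjusted p = 0.0289, 0.603 with an estimated correlation). Among these were Scn4b (1.81 ± 0.39) up and Scn3a (-0.54 ± 0.14), a sodium channel of immature neurons, down. Glucocorticoid-responsive genes rose in 5 of 16 (6 over the list alone; adjusted p = 0.0129, 0.603 with an estimated correlation). Examples were Plin4 (1.58) and Sgk1 (0.78). In the interferon list, 2 of 30 rose, Xaf1 (1.23) and Sp100 (0.73) (2 over the list alone; adjusted p = 0.00472, 0.603 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 24 (5 over the list alone; adjusted p = 0.0129, 0.603 with an estimated correlation). The pathway's regulator Srebf2 (-0.38) was a called member. The lists of pericytes, optic tract and chiasm glia, ependymal cilia, disease-associated microglia, MHC class I and endothelium were called as well, with adjusted p = 0.579, 0.579, 0.665, 0.603, 0.603 and 0.603 with an estimated correlation. Kiss1 (-0.71 ± 0.53, adjusted p = 0.4) and Agrp (-0.82 ± 0.33, adjusted p = 0.0889) did not pass the test.

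The comparison turned on the 2-month libraries. With 6 months in their place, 2896 genes differed from 5 weeks, of which 1155 were shared in direction with the 2802; the median of the hypothalamic transcription factors was then -0.32 (interval -0.62 to -0.02) in place of -1.35 (-1.74 to -0.66), while the 21 markers picked from the 2-month values stood at 1.92 (0.87 to 2.56; 20 tested) in place of 2.90. With 1 surrogate variable 944 genes were called, and with the midbrain and hindbrain level as a covariate 276. As the markers of that covariate were picked from the 2-month values, a loss of calls with it could be foreseen and is no separate support.

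**Figure D4:**
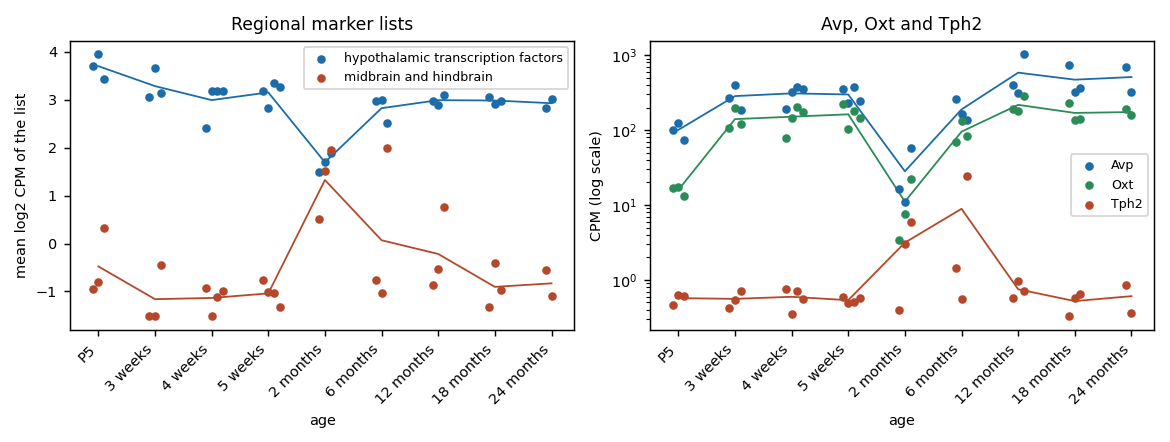
Mean log2 CPM of hypothalamic transcription factors and of midbrain and hindbrain markers (left), and CPM of Avp, Oxt and Tph2 (right), in 28 libraries by age. The 2-month libraries lie lowest in hypothalamic transcription factors and Avp, and Tph2 is high in single libraries of 2 and 6 months.

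Adult ageing was examined by comparing 24 months (2 libraries) with 2 months (3), and both with 12 months (3). Between 12 and 2 months 2675 genes changed (1262 up and 1413 down), and 31 with 1 surrogate variable or 1056 without 2-month replicate 11. Between 24 and 12 months edgeR called 1 gene, the 7SL RNA copy Rn7s2 (8.40, adjusted p = 0.0413; 701 genes at unadjusted p below 0.05). DESeq2 called 6, Rn7s1, Rn7s2, Nr4a1 (0.82), Btaf1 (-0.90), Ide (-1.15) and 4931408D14Rik, named here after their values were seen. With 6 months in place of 2 months, 12 months differed in 0 genes by edgeR (1767 at unadjusted p below 0.05) and in 41 by DESeq2.

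Between 2 and 24 months the genes of myelin fell, and some genes of microglial and astrocyte reaction rose while others did not. Mog, a myelin surface protein, fell from 210 ± 32 to 76.2 ± 6.08 CPM (-1.46 ± 0.15, adjusted p = 7.15e-06) and Cldn11, of the tight junctions in myelin, from 452 ± 66.0 to 157 ± 9.32 CPM (-1.52 ± 0.18, adjusted p = 2.15e-05). Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, rose from 22.1 ± 0.861 to 55.9 ± 5.33 CPM (1.34 ± 0.15, adjusted p = 1.1e-05). Itgax, the integrin CD11c, rose from 0.166 ± 0.0908 to 1.81 ± 0.275 CPM (3.45 ± 0.41, adjusted p = 2.15e-05), and the protocadherin Pcdhb9 from 11.5 ± 0.116 to 26.3 ± 3.54 CPM (1.20 ± 0.12, adjusted p = 6.07e-06). In all, 1932 genes changed (931 up and 1001 down, of which 309 and 178 by at least 2-fold).

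Of 22 myelin genes, 20 fell and none rose (22 over the list alone, median -1.07, adjusted p = 1.01e-34, 0.0307 with an estimated correlation). Among these were Mal (-1.19 ± 0.17), Tspan2 (-1.08 ± 0.15) and Mbp, from 8940 ± 2440 to 3960 ± 759 CPM (-1.17 ± 0.22, adjusted p = 0.00144). Oligodendrocyte precursor genes fell in 6 of 14 cases (7 over the list alone, median -0.39, adjusted p = 7.96e-05, 0.128 with an estimated correlation). Examples were Enpp6 (-1.20), Bmp4 (-1.79) and Olig2 (-0.62). Perineuronal net and matrix genes fell in 8 of 14 (9 over the list alone, median -0.54, adjusted p = 5.2e-06, 0.0391 with an estimated correlation). Called members included aggrecan, Acan (-1.15), neurocan, Ncan (-0.59), and the matrix protease Adamts4 (-0.89). Of 20 ion channel genes, 9 fell and 2 rose (10 and 2 over the list alone; adjusted p = 0.000248, 0.234 with an estimated correlation): Kcna1 (-1.31 ± 0.28) fell, and Scn3a rose (0.73 ± 0.16). Of 30 synaptic genes, 3 fell, Vamp1 (-1.11), Cplx1 (-1) and Cplx2 (-0.69) (3 over the list alone; adjusted p = 0.0263, 0.518 with an estimated correlation).

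Of 22 clustered beta protocadherins, 11 rose and none fell (13 over the list alone, median 0.57, adjusted p = 5.86e-15, 0.00944 with an estimated correlation). Among these were Pcdhb14 (1.03 ± 0.13), Pcdhb6 (1.22 ± 0.21) and Pcdhb1 (3.66 ± 0.55, 0.112 to 1.49 CPM); these cell adhesion genes are close copies, and reads shared between them were not told apart. MHC class I presentation genes rose in 9 of 19 cases (12 over the list alone, median 0.50, adjusted p = 6.25e-08, 0.153 with an estimated correlation), with the immunoproteasome subunit Psmb8 (0.97), the peptide transporter Tap1 (1.04) and H2-Q6 (2.08), while B2m did not pass the test (0.27 ± 0.15, adjusted p = 0.253). Interferon-response genes rose in 2 of 30, Lgals3bp (0.90) and Oasl2 (1.05) (2 over the list alone, median 0.38, adjusted p = 9.2e-05, 0.354 with an estimated correlation), and Ifi27 had 0.45 ± 0.28 (adjusted p = 0.326). Complement genes rose in 5 of 17 (5 over the list alone; adjusted p = 0.00767, 0.34 with an estimated correlation, up to 0.0863 without 1 library). Called were C4b, from 26.7 ± 3.92 to 79.1 ± 12.4 CPM (1.56 ± 0.34, adjusted p = 0.00477), C3 (2.34 ± 0.36) and the first component genes C1qb (0.48) and C1qc (0.50). In the disease-associated microglia list 5 of 22 rose, among them Clec7a (2.56 ± 0.42), Cst7 (2.62 ± 0.48) and Trem2 (0.61), and 4 fell, Axl, Spp1, Cd9 and Fth1 (9 and 4 over the list alone; adjusted p = 0.00767, 0.415 with an estimated correlation, up to 0.122 without 1 library). Spp1 and Fth1 are also made outside microglia.

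Reactive astrocyte genes rose in 7 of 19 cases (8 and 2 fallen over the list alone; adjusted p = 0.000624, 0.234 with an estimated correlation), with Cd109 (1.40) and Fbln5 (1.13), while Gfap did not pass the test (-0.27 ± 0.40, adjusted p = 0.706). Other astrocyte genes fell in 8 of 18 cases and Slc1a3 rose (13 and 1 over the list alone; adjusted p = 3.71e-06, 0.178 with an estimated correlation). The water channel Aqp4 (-0.94) was a called member. Pericyte and smooth muscle genes fell in 9 of 13 (12 over the list alone, median -0.87, adjusted p = 3.23e-10, 0.0695 with an estimated correlation). Among these were Tagln (-1.65) and Pdgfrb (-0.58). Endothelial genes fell in 5 of 17 (13 over the list alone; adjusted p = 4.88e-07, 0.124 with an estimated correlation). Fibroblast genes fell in 3 of 14 (9 over the list alone, median -1.56, adjusted p = 4.65e-06, 0.329 with an estimated correlation). Examples were the collagens Col3a1 (-2.82 ± 0.59) and Col1a2 (-1.66 ± 0.50). Nuclear respiratory chain genes fell in 12 of 56 (35 over the list alone, median -0.27, adjusted p = 6.79e-12, 0.364 with an estimated correlation). Mitochondrially encoded genes fell in 7 of 13 (9 over the list alone; adjusted p = 5.2e-06, 0.234 with an estimated correlation). Cilia genes of the ependyma rose in 7 of 20 (14 over the list alone, median 1.02, adjusted p = 1.36e-08, 0.291 with an estimated correlation). Rsph4a (1.45) was a called member. The thyroid hormone-responsive list had 5 of 15 fallen and 2 risen (8 and 3 over the list alone; adjusted p = 0.0329, 0.178 with an estimated correlation), and Dio2, the enzyme that activates thyroid hormone, fell from 40.9 ± 7.06 to 12.2 ± 3.16 CPM (-1.75 ± 0.27, adjusted p = 0.000353).

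Hypothalamic genes rose from the low level of the 2-month libraries. Of 30 neuropeptides, 12 rose and Grp fell (15 and 2 over the list alone, median 1.12, adjusted p = 1.18e-11, 0.048 with an estimated correlation). Among these were Avp (4.19 ± 0.63), Oxt (3.99 ± 0.53), Gal (1.90 ± 0.27) and Pomc (1.80, adjusted p = 0.0121). Of 25 transcription factors, 12 rose and Sox14 fell (14 and 1 over the list alone, median 1.35, adjusted p = 1.18e-09, 0.0695 with an estimated correlation). Puberty and reproductive genes rose in 9 of 22 cases and Mkrn3 fell (13 and 1 over the list alone; adjusted p = 3.77e-08, 0.0485 with an estimated correlation). Tac2 (1.64) was an example. Agrp (0.98 ± 0.37, adjusted p = 0.0875) and Gnrh1 (2.23 ± 0.74, adjusted p = 0.0521) did not pass the test. In the same libraries 9 of the 21 midbrain and hindbrain markers picked from these data fell and 1 rose, with Tfap2b (-4.16), Gata3 (-4.09) and Ucn (-4.50). Called at the preset correlation alone were also extracellular matrix and optic tract and chiasm glia (down) and the lists of energy balance, imprinted growth, homeostatic microglia and neutrophil genes (up), with adjusted p = 0.242, 0.178, 0.136, 0.221, 0.586 and 0.336 with an estimated correlation. Cdkn2a, a senescence marker, was too low to test, with 10 counts at 24 months and 1 at 2 months (ratio 13.8, interval 1.97 to 600).

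The count of changed genes rested on few libraries. Against 6 months (3 libraries) in place of 2 months, 17 genes differed at 24 months, 16 of them among the 1932, and DESeq2 called 130; without 24-month replicate 2 the comparison with 2 months gave 302 genes. Rn7s2 stood at 59 and 60 CPM in the 24-month libraries against at most 5.74 in those of 2 to 18 months, and replicate 2 held more of the acute-phase gene Lrg1 (7.92 CPM) and of Vwf, of endothelium and platelets (57.3), than replicate 4 (0.152 and 15.1).

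The adult age trend asked which genes moved with age over the 14 libraries from 2 to 24 months. Among the rising genes, Pcdhb9 gained 0.0508 ± 0.00525 log2 units per month (adjusted p = 0.000711), Serpina3n 0.0682 ± 0.00838 (0.00151), and Maob, which breaks down dopamine and other amines, 0.0453 ± 0.00639 (0.003; 53.2 ± 1.08 CPM at 2 months and 111 ± 6.10 at 24 months). Clec7a (0.125 ± 0.0154) and Itgax (0.163 ± 0.0210) of disease-associated microglia rose too. The potassium channel subunit Kcnab3 fell by 0.0826 per month (78.7 ± 12.0 to 19.9 ± 5.13 CPM, adjusted p = 0.00156), Dio2 by 0.0722 and Fgf11 by 0.0456, and Bche, butyrylcholinesterase, by 0.0378. In all, 1236 of 16633 genes had a slope, 512 up and 724 down, with 443 to 1557 when 1 library was left out and 248 with 1 surrogate variable.

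Myelin genes fell in 20 of 22 cases (22 over the list alone, median -0.0451, adjusted p = 7.59e-28, 0.114 with an estimated correlation). Called members included Opalin (-0.0461) and Cldn11 (-0.0638). Precursor genes fell in 7 of 14 (8 over the list alone; adjusted p = 1.41e-05, 0.03 with an estimated correlation). Among these were Enpp6 (-0.0570) and Sox10 (-0.0276). Perineuronal net genes fell in 7 of 14 (9 over the list alone; adjusted p = 1.95e-07, 0.03 with an estimated correlation). Examples were the link protein Hapln1 (-0.0696) and Ncan (-0.0256). Beta protocadherins rose in 12 of 22 (12 over the list alone, median 0.0241, adjusted p = 6.11e-18, 0.0265 with an estimated correlation). Called members included Pcdhb14 (0.0434), Pcdhb5 (0.0431) and Pcdhb13 (0.0486). The lists of precursors, perineuronal nets and protocadherins kept their call with an estimated correlation, and no other list did.

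MHC class I genes rose in 9 of 19 cases (14 over the list alone, median 0.0250, adjusted p = 7.83e-10, 0.159 with an estimated correlation). Among these were Psmb8 (0.0453) and Tapbpl (0.0205), while B2m did not pass the test (0.0169 ± 0.00687, adjusted p = 0.139). Interferon genes rose in 7 of 30 (17 over the list alone, median 0.0263, adjusted p = 9.68e-10, 0.187 with an estimated correlation). An example was Oasl2 (0.0589). Complement genes rose in 5 of 17 (6 over the list alone; adjusted p = 0.000465, 0.208 with an estimated correlation). Called members included C4b (0.0919) and C1qa (0.0256). Reactive astrocyte genes rose in 7 of 19 (8 over the list alone; adjusted p = 1.41e-05, 0.187 with an estimated correlation), while Gfap did not pass the test (-0.00541 ± 0.0179, adjusted p = 0.878). In the disease-associated microglia list 8 of 21 rose and 2 fell (9 and 4 over the list alone; adjusted p = 0.000363, 0.312 with an estimated correlation). Among these were Cst7 (0.146) and Lyz2 (0.0542) up and Axl and Spp1 down. Ctss, a protease of antigen processing, was the 1 risen gene of 8 in the MHC class II list (0.0320 ± 0.00478, 1 over the list alone). That list had an adjusted p of 0.0219 (0.443 with an estimated correlation). Its level per library did not pass (permutation, adjusted p = 0.275).

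Pericyte and smooth muscle genes fell in 9 of 13 cases (11 over the list alone, median -0.0378, adjusted p = 1.18e-11, 0.122 with an estimated correlation). Examples were Vtn (-0.0378) and Mylk (-0.0331). Fibroblast genes fell in 6 of 14 (10 over the list alone; adjusted p = 1.7e-08, 0.187 with an estimated correlation). The collagen gene Col3a1 (-0.122) was a called member. Ion channel genes fell in 9 of 20 (10 down and 2 up over the list alone; adjusted p = 1.27e-06, 0.159 with an estimated correlation). Among these were Kcna1 (-0.0578) and Scn4b (-0.0915). Astrocyte genes fell in 8 of 18 (13 down and 1 up over the list alone; adjusted p = 1.95e-07, 0.187 with an estimated correlation). An example was Slc7a10 (-0.0266). Mitochondrially encoded genes fell in 6 of 13 (11 over the list alone; adjusted p = 2.01e-08, 0.187 with an estimated correlation). ATP6 (-0.0368) was a called member. Neuropeptides rose in 5 of 30 (13 up and 1 down over the list alone; adjusted p = 2.9e-08, 0.0925 with an estimated correlation). Among these were Tac2, the neurokinin B gene (0.0717 ± 0.0119, adjusted p = 0.00631), Gal (0.0744) and Ghrh (0.0698). In the puberty list 5 of 22 rose and Mkrn3 (-0.0643) fell (7 and 1 over the list alone; adjusted p = 2.26e-06, 0.122 with an estimated correlation). Esr1, the estrogen receptor, rose by 0.0460. Avp (0.161 ± 0.0514, adjusted p = 0.0677), Vip (0.0590 ± 0.0185, 0.064) and the clock gene Per2 (0.0177 ± 0.00892, 0.233) did not pass the test, and none of the 19 clock genes did (list adjusted p = 0.916). Of the other called lists, those of hypothalamic transcription factors, energy balance, homeostatic microglia, neutrophils, cytokines, ependymal cilia and imprinted growth genes went up, with an adjusted p of 0.114 to 0.62 with an estimated correlation. Those of synaptic, border macrophage, endothelial, matrix, thyroid hormone-responsive, nuclear respiratory chain and optic tract genes went down, with an adjusted p of 0.146 to 0.477 with an estimated correlation. Of these, the levels per library of homeostatic microglia, imprinted growth, synaptic, border macrophage and nuclear respiratory chain genes did not pass (permutation, adjusted p = 0.24, 0.184, 0.069, 0.169 and 0.0937). Without the 2-month libraries the slope of the hypothalamic transcription factor level went from 0.0479 to 0.00627 (permutation p = 0.478). That of the puberty list level went from 0.0291 to 0.00997 (permutation p = 0.122), and that of imprinted growth genes from 0.0135 to 0.000498 (permutation p = 0.955).

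Without the 2-month libraries (11 libraries, 6 to 24 months) edgeR gave 0 trend genes (1552 at unadjusted p below 0.05, smallest adjusted p = 0.0536) and DESeq2 126; of the 1232 trend genes tested there, 1232 kept their direction, 775 at unadjusted p below 0.05, with a median slope ratio of 0.659, in libraries that the 2 fits share. Without the 24-month libraries 764 genes were called, 619 of them shared. With the midbrain and hindbrain level as a covariate 6 were called, Clec7a, Ly9, Lyz2, Pcdhb9, Pcdhb12 and Pcdhb14. The markers of that covariate were picked from the 2-month values, so a loss of calls could be foreseen.

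In GENCODE M21 (GRCm38), Mbp lies on chromosome 18 at 82475146 to 82585637, Mog on chromosome 17 at 37010743 to 37023398, Avp on chromosome 2 at 130580620 to 130582554, Oxt on chromosome 2 at 130576173 to 130577054, Serpina3n on chromosome 12 at 104406729 to 104414329, Itgax on chromosome 7 at 128129547 to 128150657, and Pcdhb9 on chromosome 18 at 37400855 to 37403909.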

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

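Chosen only after the result was seen were the tests on fewer neurons, on a lasting change after 5 weeks, on the 2-month libraries and choroid plexus in the adult pattern, on list levels per library with ages left out or choroid plexus held, on other orders of the libraries, and on the library batch in genes below 4-fold and in single lists; the others were written before.

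Among 154 groups of 4 libraries, 8 held 1 library far from the other 3 (by Dixon's test of its gap over the range). Chance gives about 1 in 20 groups, or about as many. At 4 weeks, replicate 1 had a mean log2 CPM of 2.42 in hypothalamic transcription factors (others 3.18 to 3.19), -2.81 in anterior pituitary genes (-1.56 to -1.37), 4.32 in cortex and hippocampus genes (3.11 to 3.15) and -1.03 in Gnrh1 (0.81 to 1). Replicate 4 had 6.00 in cholesterol synthesis genes (6.25 to 6.26) and replicate 2 had 1.98 in Agrp (2.53 to 2.60). At 5 weeks, replicate 2 had 4.48 in DNA methylation genes (4.56 to 4.58) and replicate 1 had -3.80 in Cst7 (-2.51 to -2.41). In 24-month replicate 5, which was left out of the comparisons, 111 of the 113 trend genes with at least 10 counts (98.2%) lay on the side of the other 24-month libraries, against 885 of 1076 other genes (82.2%).

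The first pattern is the low level of hypothalamic and the high level of midbrain and hindbrain transcripts at 2 months. Fewer neurons of every kind in the piece is argued against by synaptic genes, whose median log2 change from 5 weeks was 0.01 against -1.35 for hypothalamic transcription factors. A lasting fall of that size is argued against by 6 months, where those factors had a median of -0.32 against 5 weeks. A lasting change stays open for the first list of midbrain and hindbrain markers, which was still at 1.92 (interval 0.87 to 2.56). That median need not hold in each 6-month library. Tph2 stood at 24.7 CPM in 6-month replicate 34 against 1.43 and 0.56 in the others, and Pax7 at 2.72 against 0.075 and 0.56. Tissue from the midbrain and hindbrain in the piece cannot be told apart. A second list of 24 such markers, written before it was measured, had a median of 0.13. This was far below the 2.90 of the first list, which had been picked from these data. The median lay below the bound of 0.5 set beforehand for ruling such tissue out, a bound that named the median alone. The upper end of its interval (-0.20 to 0.52) passed 0.5, so the question was left undecided. Some members of the second list already stood high at 5 weeks (Gbx2 at 52 and Slc18a2 at 44.7 CPM), where added tissue would change the fold less. Others were low (Hoxd3 at 0.00973 and Irx4 at 0.104). A piece of tissue cut differently in another way stays a candidate explanation that was not tested, and age itself stays open as well, since the dissections were not marked in the labels.

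The second pattern is the adult fall of myelin genes and rise of protocadherin, MHC class I and interferon genes. Camera at the preset correlation called all lists (4) without the 2-month libraries, without the 24-month libraries, without both and with choroid plexus as a covariate, but 5, 11, 12 and 13 of 100 orders of the libraries gave as many, so the bound of 3 or 4 lists set on it (beforehand for the 24-month libraries and for both end ages) could not decide and list levels per library were used (permutation, two-sided, p adjusted over lists). The 24-month libraries as the whole cause are argued against by 2 to 18 months, where the levels of all 4 lists passed (4; permutation p = 0.0028 for myelin, 5e-05 for protocadherins, 0.00087 for MHC class I and 0.00649 for interferon genes), and choroid plexus by the levels with its own held (4; highest permutation p = 0.0043). The 2-month libraries as the whole cause are argued against for the protocadherins alone (1 of 4 lists passed over 6 to 24 months; permutation p = 5e-05, slope 0.0272 per month in 11 libraries, from 0.0331), and stay open for interferon (p = 0.0215, slope 0.0314 from 0.0281), MHC class I (p = 0.0386, 0.0227 from 0.0313) and myelin genes (p = 0.0572, -0.0208 from -0.0418), whose adjusted p was 0.137, 0.179 and 0.208. Both end ages together stay open for all (0 lists passed over 6 to 18 months in 9 libraries), which does not speak for them as the cause, since the slopes were 0.0286 for protocadherins (exact p = 0.00238), 0.0468 for interferon (0.0226), 0.0324 for MHC class I (0.056) and -0.0231 for myelin genes (0.164), smaller than over 2 to 24 months in protocadherins and myelin only, and age itself remains open as well.

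The third pattern is the set of 363 genes that changed between 3 and 5 weeks. In Bpifa2 and Rn7s2, 4-week replicates 3 and 4 resembled 5 weeks and replicates 1 and 2 resembled 3 weeks. Of the 363 genes, 265 (73%) differed between these pairs in the direction of 5 against 3 weeks. Within 4 weeks, the log2 difference between these pairs followed the 5-against-3-week change with a slope of 0.59 (interval 0.36 to 0.74), as a library batch would give. In each of the other 2 pairings the slope was 0.00. For replicates 3 and 4 against 1 and 2 it was 0.79 in the 22 genes of 4-fold or more and 0.20 (0.14 to 0.24) in the 341 genes below 4-fold. These pairs had been told apart by Bpifa2 and Rn7s2, which are themselves called genes that changed by more than 4-fold. The slopes of 0.59 and 0.79 were thus partly given by the choice of pairs, and how far was not tested. The 0.20 is lower than a batch as the whole cause would give. However, the intervals resample genes of 1 contrast of 2 against 2 libraries and leave out the spread between mice. Whether a batch was the whole cause in those 341 genes is therefore not settled. With the batch as a term, chaperones had a median of -0.43 (from -0.13, adjusted p = 0.00938 with an estimated correlation) and so passed. The term is told from age by the 4-week libraries alone, 2 against 2, and it enlarged this change. For chaperones too, it therefore does not settle whether the batch alone was the cause. Blood cell genes (-1.46, from -2.12; adjusted p = 0.113), oligodendrocyte precursors (-0.33, from -0.44; 0.0821), proliferation (-0.27) and clock genes (0.14) cannot be told apart from a batch, as the term leaves few libraries to estimate age. Salivary gland RNA in 5 libraries stays open, since only 2 of 22 genes of a second salivary list followed it, Dcpp2 and Dcpp3, which are near copies of Dcpp1 in the first.

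Other splits of the same libraries were fitted in the same way. The real split gave the most genes for 5 against 3 weeks (363, highest other 6, 1 of 35 splits as large). It did so for 2 months against 5 weeks (2802, highest other 1725, 1 of 35). The same held for the test over 9 ages (12991, highest other 5137, 1 of 100) and the adult trend (1236, highest other 22, 1 of 100). These counts of genes were thus above those of every other split fitted, though 35 splits allow no p below 0.0286. For 3 weeks against P5 (1 of 10; 9986, highest other 1) and 12 against 2 months (1 of 10; 2675, highest other 0) the 10 splits are too few. Counts of called lists were matched more often, by 21 of 35 splits for 5 against 3 weeks (16, highest other 26). For 2 months against 5 weeks 4 of 35 gave as many (22, highest other 26), and chance is not excluded for either. For the trend 3 of 100 gave as many, the real order included, and the highest other reached the same 31 lists. For 3 weeks against P5, 9 of 10 splits gave as many, the real split included (17 lists, highest other 29, median of the others 22). The 10 splits are too few for a small p, but the real number of lists was not above that of most other splits. The number of lists called at the preset correlation thus says little, and the counts of genes and the tests of list levels per library carry more. In exact splits of list levels, two-sided, 10 of 51 lists had the smallest possible p of 0.0286 for 5 against 3 weeks (9 of the 16 called; 1.46 by chance) and 14 of 51 for 2 months against 5 weeks (11 of the 22).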

How the results depend on the processing

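Chosen only after the data were seen were all 29 libraries, 6 months in place of 2 months, no 2-month libraries, P5 replicate 3 alone, the library batch term and the marker covariates; the cause of each shift was not tested unless stated. Over all settings, the called named genes kept direction and call in 691 of 700 values (3 weeks against P5), 346 of 435 (5 against 3 weeks), 701 of 810 (2 months against 5 weeks), 680 of 957 (24 against 2 months) and 1314 of 1591 (trend).

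Counts that moved by more than 1.5 times were these. With 1 surrogate variable: 944 genes (2 months against 5 weeks), 31 (12 against 2 months), 0 (24 against 12 months; 834 at unadjusted p below 0.05), 40 (24 against 2 months), 248 (trend) and 7 lists (2 months against 5 weeks). With only the ages compared, which leaves fewer libraries for the spread: 1534, 362, 3 and 326 in the same order of comparisons. With DESeq2: 6 (24 against 12 months) and 2045 (trend). With no filter: 0 (24 against 12 months; 812 unadjusted). The trend on log2 age gave 3063 genes, and without 24 months 764. With all 29 libraries: 484 (9 ages), 0 (24 against 12 months; 350 unadjusted), 4 (24 against 2 months) and 0 (trend; 232 unadjusted), the added file holding part of the genes. With 6 months in place of 2 months: 0 (12 months; 1767 unadjusted, DESeq2 41), 17 (24 months; DESeq2 130) and 13 lists (2 months against 5 weeks). Without the 2-month libraries the trend gave 0 (1552 unadjusted, DESeq2 126). With the library batch term: 20 (5 against 3 weeks). With the midbrain and hindbrain covariate, whose markers were picked from the 2-month values: 276 (2 months against 5 weeks), 371 (24 against 2 months), 6 (trend) and 11 lists (2 months against 5 weeks). With an estimated correlation, called lists numbered 5, 5, 0, 5 and 3 (3 weeks, 5 weeks, 2 months, 24 months, trend); camera gave 22 lists for the 0.

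Leaving out 1 library at a time gave 9182 to 9390 genes (3 weeks against P5), 183 to 256 (5 against 3 weeks), 1778 to 2858 (2 months against 5 weeks), 1056 to 3231 (12 against 2 months), 0 to 7 (24 against 12 months), 302 to 2221 (24 against 2 months), 443 to 1557 (trend) and 12272 to 13191 (9 ages), and 14 to 21, 16 to 20, 18 to 26, 27 to 30 and 29 to 32 lists. Shifts above 1.5 times came without 3-week replicates 2 (183) or 1 (198), 5-week replicates 1 (221) or 4 (232), 5-week replicate 3 (2 months, 1778), 2-month replicate 11 (12 months, 1056; 24 months, 1207; trend, 718), 12-month replicate 26 (1259), 24-month replicates 2 (302) or 4 (1067), and, for the trend, 2-month replicates 13 (443) or 12 (453) and 24-month replicate 2 (508). Of the called lists, these lost their call without 1 library: 3 of 17 for 3 weeks against P5 (blood cells, disease-associated microglia, synaptic), 5 of 16 for 5 against 3 weeks (border macrophages, cholesterol, nuclear respiratory chain, striatum, thalamus), 11 of 22 for 2 months against 5 weeks (MHC class I, astrocytes, cholesterol, cytokines, disease-associated microglia, endothelium, cilia, interferon, ion channels, mitochondrially encoded, myelin), 6 of 28 for 24 against 2 months (complement, disease-associated and homeostatic microglia, neutrophils, synaptic, thyroid) and 4 of 31 for the trend (MHC class II, border macrophages, cytokines, homeostatic microglia). Where 24 months keeps 1 library, it is assumed to vary like the other ages.

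Reversed values of called genes included Chia1 0.13 (batch term), Pdyn 0.04, Ly6c1 -0.03 and Rsph4a 0.09 (6 months in place of 2 months), and Tapbpl -0.000224 (all 29 libraries). Genes that had not passed changed sign as follows. From 3 to 5 weeks, Gnrh1 had -0.06 (replicate block) and -0.65 (batch term), and Tac2 -0.02 (replicate block) and -0.04 (batch term). From 5 weeks to 2 months, Mbp had -0.13 (surrogate variable) and -0.47 (6 months), Dcx 0.43, 0.44 and 0.38 (surrogate variable, 6 months, covariate), and Kiss1 0.04 and 0.34 (6 months, covariate). At 24 months, Gfap had 0.03 (surrogate variable) and 0.28 (6 months), B2m -0.33 and Ifi27 -0.15 (29 libraries). In the trend, Gfap had 0.00253 (surrogate variable), 0.00621 (no 2-month libraries) and 0.0148 (covariate), and B2m -0.0039 (29 libraries). Without 1 library at a time, Igf2 ranged from -0.56 to 0.23 and Gnrh1 from -0.19 to 1.08 (3 weeks against P5), Gnrh1 from -0.22 to 0.54, Tac2 from -0.09 to 0.14 and Lin28b from -0.01 to 0.14 (5 against 3 weeks), Mbp from -0.01 to 0.35 and Dcx from -0.27 to 0.18 (2 months against 5 weeks), and Gfap from -0.0109 to 0.00234 (trend).

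Replicate numbers are shared by some ages, but did not pair the libraries: the mean correlation of same-numbered deviations was 0.01 (-0.21 to 0.13, 19 pairs), and 3 of 14 libraries correlated best with their own number. With the replicate block, 10243 genes were called for 3 weeks against P5 and 251 for 5 against 3 weeks, with 23 and 19 lists.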

Other observations

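The tests and genes of this part were all chosen after the values were seen. Between 6 and 24 months (3 and 2 libraries) 17 genes differed by edgeR. Among them were 3 genes of activated microglia, Itgax from 0.401 ± 0.0543 to 1.81 ± 0.275 CPM (2.17 ± 0.35, adjusted p = 0.0343), Clec7a, a pattern recognition receptor, from 0.537 ± 0.0840 to 2.50 ± 0.798 (2.20 ± 0.41) and Cst7, a cystatin, from 0.179 ± 0.0172 to 0.924 ± 0.0623 (2.34 ± 0.43). Serpina3n rose from 30.3 ± 2.65 to 55.9 ± 5.33 CPM (0.88 ± 0.15, adjusted p = 0.0343). Protocadherins of the clusters on chromosome 18 rose as well, Pcdhb3 (0.63), Pcdhb8 (0.96), Pcdhb9 (0.68), Pcdhb14 (0.72) and, of the alpha cluster, Pcdha5 (0.78). Fdft1, of cholesterol synthesis, rose by 0.41, and Rn7s2 by 6.18. Kcnab3 fell from 48.4 ± 13.1 to 19.9 ± 5.13 CPM (-1.29 ± 0.24), Prom1 from 12.5 to 7.17 (-0.81 ± 0.14), and Abcc6 (-1.68), Slc6a8, the creatine transporter (-0.45), Zfp521 (-0.44) and Syt3 (-0.41) fell too. The libraries of the 2 ages did not overlap in any of the 17 genes, which chance gives in 20% of genes for 3 against 2. As the 17 genes were called from these same libraries, their lack of overlap is no separate support. Over the 11 libraries of 6 to 24 months, the level of 6 lists moved with age by permutation (two-sided, adjusted over 51 lists): protocadherins (0.0272 per month, adjusted p = 0.00255), neuropeptides (0.023, 0.0388) and energy balance genes (0.007, 0.0388) rose, and perineuronal net (-0.0156, 0.0339), oligodendrocyte precursor (-0.0135, 0.0388) and mitochondrially encoded genes (-0.0232, 0.0388) fell. The list of disease-associated microglia did not pass there (0.0326, adjusted p = 0.0991, permutation).

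Ide, the insulin-degrading enzyme, stood at 88.2 ± 3.76 CPM at 12 months and 39.8 ± 2.53 at 24 months. At 2, 6 and 18 months it was at 68.5, 69.3 and 60.3 CPM, so the level did not fall steadily with age. Ide was at 99.2 and 90.2 CPM in 4-week replicates 1 and 2 and at 66.6 and 44.5 in replicates 3 and 4. Bpifa2 and Rn7s2 part the same 2 sets. After age means were removed, the gene that correlated best with Ide among 14591 was its neighbor Btaf1 (r = 0.78), followed by 4931408D14Rik. Taken singly, their permutation p was 0.0023 and 0.0025 (two-sided), without adjustment for the 14591 genes searched. The best of all genes was as high in many shuffles within ages (permutation p = 0.352, two-sided, median of the best 0.77). Chance is thus not excluded for a best correlation of this size. How often a neighbor would rank first was not tested. Ide lies on chromosome 19 at 37268743 to 37337852 and Btaf1 at 36926079 to 37012752 (GENCODE M21, GRCm38). Fgfbp3, next to Btaf1 at 36917550 to 36919615, had r = 0.52 (p = 0.0815), while Cpeb3 (-0.27, p = 0.206) and March5 (0.19), which lie between Btaf1 and Ide, and Tnks2 (0.03, p = 0.935) did not follow. As background, a segment with Ide and Fgfbp3 is known to differ in copy number among C57BL/6J mice; no copy number was measured or tested here.

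With the library batch as a term, 20 genes differed between 3 and 5 weeks. Those of protein folding fell, Hspa5 (-0.71 ± 0.10; 419 against 319 CPM), Hsp90b1 (-0.41 ± 0.08; 464 against 380) and Pdia3 (-0.46 ± 0.08; 280 against 226), as did Traf3 (-1.07 ± 0.14; 148 against 81.2), while the cold-induced RNA-binding gene Rbm3 (0.99 ± 0.18; 28.4 against 38 CPM), Serpinb1a (2.43 ± 0.43) and Pkd2l1 (2.78 ± 0.40) rose. The term enlarged several of these folds beyond the measured difference in CPM, most for Rbm3 of those given, and Fosb, Dnajb1, Slc5a3 and Mir9-3hg were also called although their libraries of the 2 ages overlapped.

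Hcrt, the orexin gene, stood at 8.69 CPM in 18-month replicate 14 against 87.2 and 92.3 CPM in the other 18-month libraries. Tph2, of serotonin synthesis, stood at 24.7 CPM in 6-month replicate 34 against 1.43 and 0.56, and at 3.05 and 5.99 CPM in 2-month replicates 12 and 13. The share of reads of low mapping quality was 9.31 to 11.2% at 5 weeks, 9.19 and 9.27% in 4-week replicates 4 and 3, and at most 7.30% in each other library. Sele, an endothelial gene of inflammation, stood at 1.85 CPM in 24-month replicate 2 and at 0.0607 in replicate 4.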
